A study of Mus musculus with 8 samples.

How the data were processed

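Liver tissue of mice kept on a choline-deficient, amino acid-defined, high-fat diet was profiled by bulk RNA sequencing in 8 libraries. The diet produces steatohepatitis, a fatty liver with inflammation and scarring. The mice had received an intravenous injection of vesicles taken from the blood of human volunteers, either after remote limb ischemic conditioning (group RIC_hEV, 4 libraries) or after a sham procedure (group ctr_hEV, 4 libraries). Groups and replicate numbers were read from the sample titles. The labels name the tissue, the genotype and the injected vesicles. They give no animal identifier, batch, dose or time, so the p-values describe the spread between these 8 libraries, and it is not given in the sources used here whether each comes from its own mouse.

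Total RNA was extracted with Trizol and made into libraries with a universal Illumina kit from VAHTS, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1 and HTSeq 0.13.5, and the genome build mm10. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, with 1 column per library. The program that computed FPKM, the annotation, the gene lengths and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and long and short genes are comparable only as far as the unstated lengths hold.

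The table held 55335 rows. Of these, 3225 carried no gene name; they were left out of every test and took between 0.176% and 0.207% of the FPKM of a library. A further 26 rows carried symbols turned into calendar dates by a spreadsheet program; these stayed in the tests and are not named. Of 80 symbols present on more than 1 row, the row with the higher mean kept the symbol. Every per-sample column was assigned to a sample.

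Total FPKM per library lay between 389616 and 430326. Read counts were not part of the deposited values used here. FPKM times exon length (GENCODE release M21) of low genes had a most common value in each library; read as the worth of 1 fragment, it puts the depth at 23700000 to 28800000 fragments in ctr_hEV and 19300000 to 28500000 in RIC_hEV. These depths are estimates. Between 14.5% and 16.0% of values below about 20 such steps lay within 0.02 of a whole step, so most values are not whole reads over that length and no count model was used. At these depths an FPKM of 1 for a transcript of 2 kb would rest on 38.6 to 57.6 fragments.

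FPKM values were transformed to log2(FPKM + 1). Genes with a mean FPKM of at least 1 over all 8 libraries were tested, 11274 in number. RIC_hEV was compared with ctr_hEV by linear models with empirical Bayes moderation and a mean-variance trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low FPKM. The median log2 fold change of all tested genes was -0.11, so log2 changes of single tested genes are given relative to the median of the same fit. Those of genes below the filter, and those given with the alternatives, are as computed. The SE and p-values of single genes belong to the change as fitted, before the median was subtracted. They do not test the relative value, which is further from 0 for higher genes and nearer to 0 for most lower ones. Per-group values are means ± SD of FPKM over 4 libraries. Genes below the filter were compared by two-sided exact permutation tests over the 70 assignments of 8 libraries to groups of 4, for which the smallest possible p is 0.0286.

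Before the data were examined, 35 gene lists were fixed, covering steatohepatitis, other cell types of a liver piece, and signs of handling or RNA quality. Of their 862 symbols, 853 matched the table. The 9 others were not in the table and were not replaced. The 32 lists with at least 5 tested members were tested with camera in limma with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Each list also has the p with a correlation estimated from the data, and the number of members passing when adjusted over the list alone. Counts of members higher or lower use log2 changes as fitted, and a list's mean is relative to the other tested genes. As the median tested gene lay at -0.11, most tested genes were lower as fitted, which raises counts of lower members in every list. A list score is the mean log2(FPKM + 1) of the members minus that of all tested genes in a library. For the microRNA family miR-181, 3' UTRs of GENCODE M21 transcripts (mm10) were searched for the 7 bases matching positions 2 to 8, with 100 shuffled sequences of the same composition as reference.

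Genes named in the text follow a rule fixed at the same time: up to 10 genes in each direction that passed and whose groups did not overlap, largest change first, without unnamed gene models and filled by the lowest p where fewer than 10 passed; the 2 tested members of each list with the lowest p; and 20 fixed genes. Gene models that passed, and other genes outside the rule, are said to have been chosen after their values were seen. Positions are from GENCODE M21 on mm10.

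The steps were first tested on simulated data with the means and spreads of the 11274 tested genes. Noise was drawn independently for each gene, and changes were planted only in genes with a mean log2(FPKM + 1) above 2. The shares recovered therefore do not describe genes of lower FPKM, or data in which whole libraries stand apart. Of 50 genes changed by 0.5 log2 units, 50% were recovered; for 1 and 2 log2 units the shares were 88% and 98%, with 5 false calls in all. No pair of libraries was a duplicate: correlations across genes ranged from 0.958 to 0.987. The alternatives were another pseudocount, 2 other filters, 3 other scalings, library weights, a replicate block, other variants of the gene and list tests, and each library left out in turn. Leaving out ctr_hEV 1 and ctr_hEV 3 together, and a permutation test of list scores, were added after the data were seen.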

Results

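Bulk liver transcriptomes were measured in 8 libraries of mice with diet-induced steatohepatitis, 4 after injection of human circulating vesicles collected after limb conditioning (RIC_hEV) and 4 after vesicles from sham-treated volunteers (ctr_hEV). Remote limb ischemic conditioning is a series of short interruptions of blood flow to a limb. The series title states that conditioning eases steatohepatitis through vesicles, and the comparison asks how the liver transcriptome differs between both kinds of vesicle. Estimated depth was 19300000 to 28800000 fragments per library. Mitochondrially encoded transcripts took between 15% and 19% of FPKM.

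The libraries did not separate by group on the leading component. The first principal component held 44.4% of the variance; ctr_hEV 1 (-36.1) and ctr_hEV 3 (-23.3) lay at one end, ctr_hEV 2 at -2.36, and ctr_hEV 4 at 16.3 among the RIC_hEV libraries, which lay between 4.75 and 16.3.

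Of the genes higher in liver after RIC vesicles, 2 passed the threshold over all genes, and both were immunoglobulin genes. The immunoglobulin family as a whole was not tested. Ighg2c, the constant region of an IgG2 heavy chain (chromosome 12, 113285325 to 113288932, minus strand), rose from 3.73 ± 1.68 to 18.0 ± 3.94 FPKM (SD, n = 4 per group). Its log2 change was 2.16 relative to the median gene and 2.05 as fitted (SE 0.25, limma adjusted p = 0.0245 for the fitted change). Igkv3-4, a kappa light-chain variable segment (chromosome 6, 70671788 to 70672377, plus strand), rose from 0.666 ± 0.618 to 5.80 ± 1.43 FPKM. Its relative log2 change was 2.18, and 2.07 as fitted (SE 0.23, limma adjusted p = 0.0152 for the fitted change). In both genes all 4 RIC_hEV libraries lay above every ctr_hEV library. Igkv3-4 shares 55.2% of its 31-base stretches with other annotated genes, so its level is uncertain. Ighg2c did not pass without RIC_hEV 1, 3 or 4 (adjusted p of 0.123, 0.127 and 0.155), and Igkv3-4 did not pass without RIC_hEV 3 or 4 (0.0592 and 0.117).

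Some further genes of antibody-secreting cells were higher without passing. Igkc, the kappa constant region, was at 18.9 ± 5.30 FPKM in ctr_hEV and 44.9 ± 5.20 in RIC_hEV (limma adjusted p = 0.134). Jchain, which joins secreted IgA and IgM, was at 1.31 ± 0.394 and 3.03 ± 0.596 FPKM (limma adjusted p = 0.235). Ighv1-9 (limma adjusted p = 0.118) was listed at 0 in ctr_hEV 1, 2 and 3, at 0.652 FPKM in ctr_hEV 4, and at 1.21 to 3.03 in RIC_hEV. Of the B and plasma cell list, 4 members were measured, too few for the list test; Igkc and Jchain passed when adjusted over the list alone and none passed over all genes. The T and NK cell list also had 4 tested members and none passed over either.

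**Figure D1:**
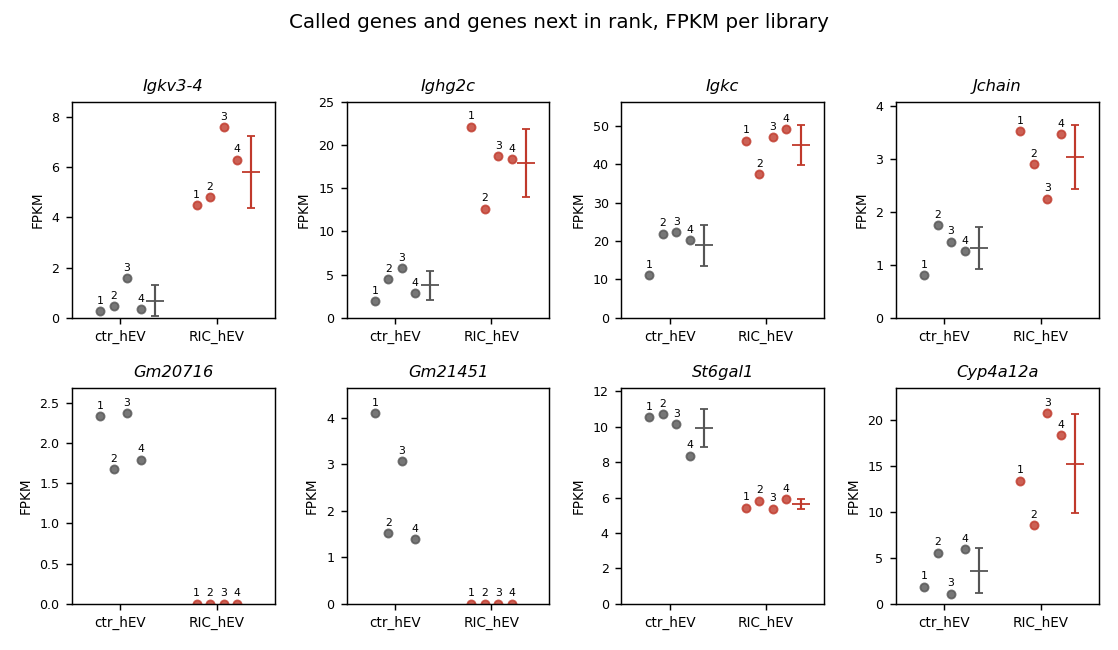
FPKM (vertical axis, from 0) of 8 genes in each library; points are libraries with replicate numbers, and bars give the mean ± SD of 4 libraries except where a group is listed at 0. The immunoglobulin genes shown lie higher in RIC_hEV (Ighg2c at 3.73 and 18.0 FPKM on average), and Gm20716 and Gm21451 are listed at 0 in all 4 RIC_hEV libraries.

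In all, 4 of the 11274 tested genes passed, 2 higher and 2 lower in RIC_hEV. Both genes that passed as lower are gene models, chosen for naming after their values were seen. Gm20716 (chromosome 2, 168180986 to 168230364, minus strand), annotated as protein-coding and overlapping Adnp and Dpm1, was at 2.34, 1.68, 2.37 and 1.80 FPKM in ctr_hEV 1 to 4 and listed at 0 in every RIC_hEV library (limma adjusted p = 0.000279). Gm21451, an unprocessed pseudogene (chromosome 14, 69390854 to 69480287, plus strand), was at 4.09, 1.52, 3.07 and 1.39 FPKM and likewise listed at 0 (limma adjusted p = 0.0262). Of their 31-base stretches, 99.5% and 98.9% also occur in another annotated gene, so both levels are uncertain. Gm20716 passed with each library left out, at an adjusted p of at most 0.00359, whereas Gm21451 did not pass without ctr_hEV 3, RIC_hEV 1, RIC_hEV 2, RIC_hEV 3 or RIC_hEV 4 (0.0969 to 0.155). The count depended on single libraries: it was 176 without ctr_hEV 4 (41 higher, 135 lower), 2 without RIC_hEV 1 and 1 without RIC_hEV 3 or RIC_hEV 4, where only Gm20716 passed.

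At an unadjusted p under 0.05 there were 1576 genes, against 564 expected by chance. Of these, 297 were higher and 1279 lower in RIC_hEV, but with per-library median centring 918 were higher and 438 lower, with quantile normalization 605 and 607, and on a TPM scale 195 and 1588. There were 587 without ctr_hEV 1 and ctr_hEV 3 (218 higher, 369 lower). Splits that exchanged ctr_hEV 4 for RIC_hEV 2, RIC_hEV 3 or RIC_hEV 4 gave 1614, 2026 and 3279 such genes, so the count does not set the groups apart from other divisions of the libraries. The groups did not overlap in 662 genes (5.87%, where chance gives 2.86% on average over splits). Of these, 148 were higher and 514 lower in RIC_hEV. The share in each other split is not given here, so the excess does not set the groups apart.

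The other genes named by rank did not pass. St6gal1, a sialyltransferase of secreted glycoproteins, was at 9.94 ± 1.07 FPKM in ctr_hEV and 5.63 ± 0.268 in RIC_hEV. Its relative log2 change was -0.61, and -0.72 as fitted (SE 0.10, limma adjusted p = 0.0653 for the fitted change). Ugcg, which makes glucosylceramide, was at 11.3 ± 0.797 and 7.45 ± 0.607 FPKM. Mmp13, a collagenase, was at 4.93 ± 0.960 and 2.64 ± 0.250, and the acute-phase protein Lcn2 at 246 ± 74.0 and 117 ± 8.72; these 3 and Zfp655 shared an adjusted p of 0.214. Among the increases, the fatty acid omega-hydroxylases Cyp4a12a (3.59 ± 2.48 and 15.2 ± 5.42 FPKM; limma adjusted p = 0.306) and Cyp4a12b (5.01 ± 3.88 and 18.2 ± 3.0 FPKM; limma adjusted p = 0.332) share 62.2% and 62.9% of their 31-base stretches with other genes. Their relative log2 changes of 2.05 and 2.05 went to 1.23 and 1.06 without ctr_hEV 1 and ctr_hEV 3 together, and both passed without ctr_hEV 4 (adjusted p = 0.0435, against 0.168 to 0.636 with another library left out). Setd6, Serpina11, Igkv1-110, Ugdh, Cdpf1, Ugt2b35, Nat8f4 and Pip5k1c complete the 20 genes; the groups did not overlap in any of them and none passed. Igkv1-110 shares 63.6% of its 31-base stretches with other genes.

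Across gene lists, 20 of 32 were called with the preset correlation, 15 higher and 5 lower in RIC_hEV relative to other genes. None was called with an estimated correlation (lowest adjusted p = 0.0926, with 6 lists at an unadjusted p under 0.05), with fry (8 lists at an unadjusted p under 0.05) or in exact permutation tests of list scores (5 lists at an unadjusted p under 0.05, all at the smallest possible p of 0.0286, adjusted p = 0.183). The list changes below are therefore calls of the preset test only.

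Fatty acid oxidation and nuclear oxidative phosphorylation genes lay higher after RIC vesicles. Of 36 measured genes of fatty acid oxidation and PPAR alpha targets, 34 were higher and 2 lower, with a mean 0.32 log2 units above the other genes (preset adjusted p = 3.33e-17, adjusted p = 0.103 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Angptl4, an inhibitor of lipoprotein lipase, was at 44.0 ± 5.86 FPKM in ctr_hEV and 59.7 ± 4.45 in RIC_hEV (limma adjusted p = 0.332). Cpt1a, the entry step of mitochondrial oxidation, was at 122 ± 16.6 and 126 ± 15.1, Ppara at 33.4 ± 3.48 and 32.0 ± 5.67, and the hormone Fgf21 at 39.54 ± 20.48 and 25.3 ± 5.88. The relative log2 change of Fgf21 turned from -0.40 to 0.15 without ctr_hEV 1 and ctr_hEV 3. Nuclear genes of oxidative phosphorylation were higher in 33 of 37 (mean 0.22 above other genes; preset adjusted p = 6.23e-13, adjusted p = 0.159 with an estimated correlation), with Ndufb10 at 53.4 ± 6.22 and 72.2 ± 1.10 FPKM and Cyc1 at 62.6 ± 3.10 and 73.9 ± 5.84. The 13 mitochondrially encoded genes, a list kept for signs of handling or RNA quality, had 12 higher (mean 0.27; preset adjusted p = 5.34e-06, adjusted p = 0.415 with an estimated correlation), and were no longer called without ctr_hEV 1 and ctr_hEV 3 together (mean 0.081). The means of the fatty acid oxidation and nuclear oxidative phosphorylation lists were then 0.20 and 0.10 and still called.

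Heat-shock genes, a list kept for signs of stress or handling, were higher in 17 of 17 (mean 0.56 log2 units above the other genes; preset adjusted p = 2.78e-16, adjusted p = 0.159 with an estimated correlation). None passed over all genes and 9 passed adjusted over the list alone. The chaperone Hspa1b was at 55.7 ± 27.0 FPKM in ctr_hEV and 118 ± 29.7 in RIC_hEV and the small heat-shock protein Hspb1 at 45.4 ± 22.1 and 89.6 ± 15.9. They share 68.1% and 55.4% of their 31-base stretches with other genes. The list scores of all 4 RIC_hEV libraries lay above every ctr_hEV library. The mean was 0.27 and still called without ctr_hEV 1 and ctr_hEV 3 together.

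Hepatocyte functions were also called higher with the preset correlation. Hepatocyte identity genes were higher in 20 of 24 (mean 0.26; preset adjusted p = 1.42e-08, adjusted p = 0.159 with an estimated correlation); 2 members passed adjusted over the list alone, including the tyrosine-degrading enzyme Hpd (443 ± 71.8 and 686 ± 88.5 FPKM). Periportal genes were higher in 15 of 18 (mean 0.31; preset adjusted p = 2.01e-06, adjusted p = 0.242 with an estimated correlation), with Asl of the urea cycle at 78.4 ± 15.0 and 122 ± 19.5 and Tat at 737 ± 290 and 1166 ± 120. Genes of gluconeogenesis and insulin response were higher in 17 of 25 (mean 0.40; preset adjusted p = 1.53e-07, adjusted p = 0.216 with an estimated correlation). In that list the liver glycogen synthase Gys2 passed adjusted over the list alone, at 159 ± 14.5 and 218 ± 18.3. Genes of lipoprotein export and phosphatidylcholine synthesis, a route that lack of choline limits, were higher in 17 of 23 (mean 0.18; preset adjusted p = 4.83e-05, adjusted p = 0.0926 with an estimated correlation), with Mat1a at 1458 ± 117 and 1847 ± 205. Ahcy, at 472 ± 109 and 721 ± 86.7, shares 71.4% of its 31-base stretches with other genes. Without ctr_hEV 1 and ctr_hEV 3 together the periportal list was still called, while the means of the identity, gluconeogenesis and lipoprotein lists were 0.072, 0.25 and 0.075 and no longer called.

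Differences were also called in 7 other lists. Xenobiotic P450 genes (16 of 26 higher, mean 0.23), pericentral genes (11 of 17, mean 0.25) and interferon response genes (19 of 34, mean 0.13) were called higher at preset adjusted p of 0.000368, 0.000901 and 0.000443. Their adjusted p were 0.452, 0.447 and 0.447 with an estimated correlation. Without ctr_hEV 1 and ctr_hEV 3 together these 3 means turned to -0.28, -0.14 and -0.049, and the P450 list was called lower (preset adjusted p = 0.00336). Ribosomal protein genes, also kept for signs of RNA quality, were higher in 20 of 39 (mean 0.10; preset adjusted p = 0.00352, adjusted p = 0.735 with an estimated correlation), a direction that turned to -0.029 with quantile normalization. Sinusoidal endothelial genes were higher in 12 of 18 (mean 0.14; preset adjusted p = 0.00408, adjusted p = 0.480 with an estimated correlation), and genes of de novo lipogenesis in 14 of 26 (mean 0.12; preset adjusted p = 0.0174, adjusted p = 0.423 with an estimated correlation). Lipid droplet and uptake genes were called higher relative to other genes (mean 0.085; preset adjusted p = 0.0447, adjusted p = 0.522 with an estimated correlation), although their median and mean log2 changes were -0.031 and -0.013 and 12 of 21 were lower. In that list 4 members were higher and 2 lower adjusted over the list alone; the latter were Pparg (8.33 ± 1.98 and 5.16 ± 0.678 FPKM) and Vldlr (1.36 ± 0.181 and 0.723 ± 0.202). In lipogenesis, Fasn was at 3.49 ± 0.434 and 3.11 ± 0.402, Scd1 at 363 ± 50.2 and 402 ± 89.0, and Srebf1 at 7.54 ± 4.76 and 3.85 ± 0.126. The relative log2 change of Srebf1 turned from -0.52 to 0.14 without ctr_hEV 1 and ctr_hEV 3. Single libraries decided all 7 calls. Leaving out ctr_hEV 1 ended the calls of the P450 (0.041), pericentral (0.11), lipogenesis (0.093) and lipid droplet lists (0.089), and leaving out ctr_hEV 3 those of the pericentral (0.13), interferon (0.027) and lipogenesis lists (0.093). Leaving out RIC_hEV 4 ended the endothelial (0.090) and lipid droplet calls (0.087). Leaving out RIC_hEV 3 ended the ribosomal (0.039) and lipid droplet calls (0.056), and leaving out RIC_hEV 2 the ribosomal call (0.074). Without RIC_hEV 1 the lipogenesis (0.065) and lipid droplet lists (0.065) were not called, nor was the latter without ctr_hEV 4 (0.057).

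**Figure D2:**
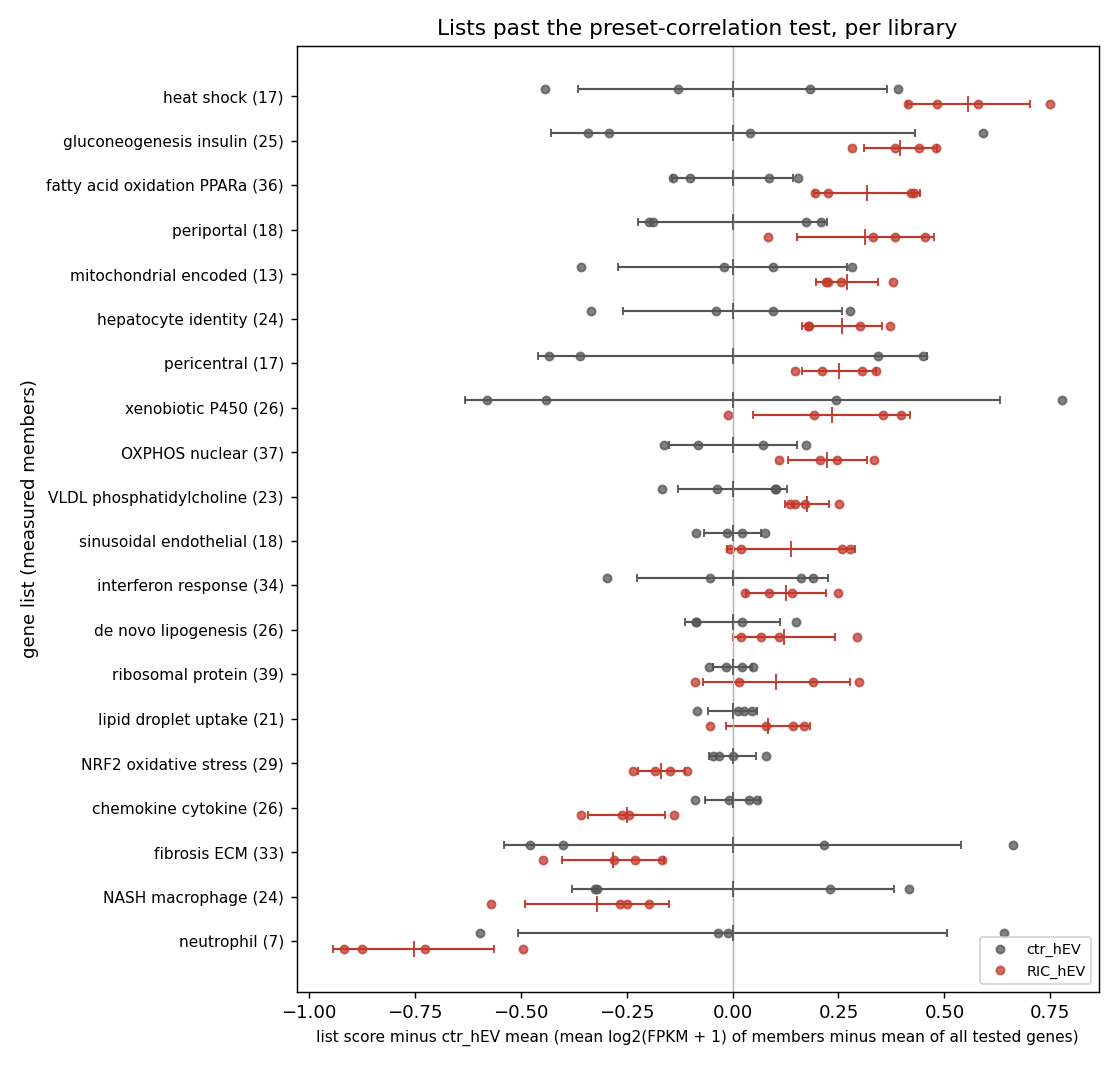
List scores per library for the 20 lists called with the preset correlation; the horizontal axis is the score minus the ctr_hEV mean in log2 units, points are libraries and bars the mean ± SD of 4 libraries. Chemokine and NRF2 scores lie lower in all 4 RIC_hEV libraries than in every ctr_hEV library, while ctr_hEV libraries spread widely in the fibrosis, macrophage and P450 lists.

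Inflammatory genes lay lower after RIC vesicles. Of 26 chemokine and cytokine genes, 22 were lower (mean -0.25 log2 units against other genes; preset adjusted p = 0.000225, adjusted p = 0.415 with an estimated correlation). None passed over all genes and 11 passed adjusted over the list alone, all lower, among them the interleukin Il1b at 2.54 ± 0.363 FPKM in ctr_hEV and 1.48 ± 0.290 in RIC_hEV, and the monocyte chemokines Ccl2 at 9.26 ± 0.937 and 5.39 ± 2.06 and Ccl7 at 2.10 ± 0.561 and 0.982 ± 0.187. Of 16 neutrophil genes 7 were tested, and 7 of 7 were lower (mean -0.75, preset adjusted p = 0.00204, adjusted p = 0.415 with an estimated correlation). The filter admits members such as Ngp (2.40 and 0.326 FPKM, chosen after its values were seen) through their ctr_hEV values. The 7 of 7 is therefore partly set by the filter. Adjusted over the list alone, 5 passed. S100a9 was at 18.3 ± 12.2 and 4.69 ± 2.66, and S100a8 at 11.8 ± 7.22 and 3.61 ± 0.803. The neutrophil mean went to -0.45 without ctr_hEV 1 and ctr_hEV 3 together, and the relative log2 change of S100a8 from -1.20 to -0.70. Antioxidant genes of the NRF2 response were lower in 24 of 29 (mean -0.17; preset adjusted p = 0.00863, adjusted p = 0.447 with an estimated correlation), with 3 passing adjusted over the list alone, including Gsta2 (50.6 ± 9.51 and 29.8 ± 7.84, with 60.7% of its 31-base stretches shared) and Ugdh (36.0 ± 5.44 and 21.7 ± 2.59).

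Macrophage and matrix genes lay lower on average, but the means of both lists rested on 2 control libraries. NASH macrophage genes were lower in 23 of 24 (mean -0.32; preset adjusted p = 0.00208, adjusted p = 0.660 with an estimated correlation) and fibrosis genes in 33 of 33 (mean -0.28; preset adjusted p = 0.00863, adjusted p = 0.735 with an estimated correlation). Without ctr_hEV 1 and ctr_hEV 3 these means were 0.0019, no longer called, and 0.16, called higher in RIC_hEV (preset adjusted p = 7.51e-05). These 2 libraries were picked after the data were seen and hold the highest scores of both lists. Leaving them out therefore had to raise both means. Library weights estimated from the data were lowest for ctr_hEV 4 (0.39) and highest for ctr_hEV 3 (2.47). The fibrosis call also ended without ctr_hEV 1 (-0.061), ctr_hEV 3 (-0.21) or RIC_hEV 2 (-0.23) alone. Of the fibrosis list 1 member, Mmp13, passed adjusted over the list alone, and its relative log2 change of -0.58 was -0.66 without both libraries. No macrophage gene passed in that way. Col1a1, the main scar collagen, was at 32.7, 4.97, 14.9 and 5.85 FPKM in ctr_hEV 1 to 4 and between 5.99 and 11.7 in RIC_hEV (limma adjusted p = 0.679). Its relative log2 change was -0.27, and -0.38 as fitted (SE 0.47). Without ctr_hEV 1 its relative change was 0.18. Col3a1 was at 34.9 ± 27.1 and 19.5 ± 4.43 FPKM, Acta2 at 7.17 ± 3.63 and 4.37 ± 1.10, Timp1 at 6.51 ± 4.42 and 3.14 ± 0.858 and Tgfb1 at 6.08 ± 1.75 and 5.39 ± 0.484. The relative log2 changes of these genes were -0.41, -0.40, -0.58 and -0.0083. They turned to 0.40, 0.087, 0.031 and 0.18 without ctr_hEV 1 and ctr_hEV 3 together. The macrophage marker Adgre1 was at 25.0 ± 6.55 and 21.02 ± 2.71, Mmp12 at 39.1 ± 10.8 and 23.6 ± 5.67, and the scavenger receptor Cd36 at 122 ± 30.7 and 87.0 ± 16.8. None of these genes passed.

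The nuclear receptors of the NR4A family, induced early in inflammation, were examined as fixed genes. Nr4a1 was at 7.08 ± 4.04 FPKM in ctr_hEV and 4.40 ± 1.06 in RIC_hEV (limma adjusted p = 0.446). Nr4a3 (chromosome 4, 48045153 to 48086447, plus strand) lay below the filter at 0.443 ± 0.0591 and 0.249 ± 0.00701 FPKM, lower in 4 of 4 RIC_hEV libraries than in every ctr_hEV library (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0571 over the 4 fixed genes below the filter). Tnf, at 1.27 ± 0.271 and 0.712 ± 0.139, gave the same exact permutation p. Nr4a2 was at 0.534 ± 0.268 and 0.427 ± 0.132 (exact permutation p = 0.543), and Il6 lay at 0.0804 FPKM or below in every library (exact permutation p = 1.0). With per-library median centring the log2 difference of Nr4a3 went from -0.21 to -0.073 (exact permutation p = 0.543) and that of Tnf from -0.40 to -0.27 (exact permutation p = 0.0571). Centring shifts all genes of a library by the same amount on the log2(FPKM + 1) scale. It therefore moves genes near 0 FPKM more than a rescaling of FPKM would, and does not decide whether these genes differ.

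**Figure D3:**
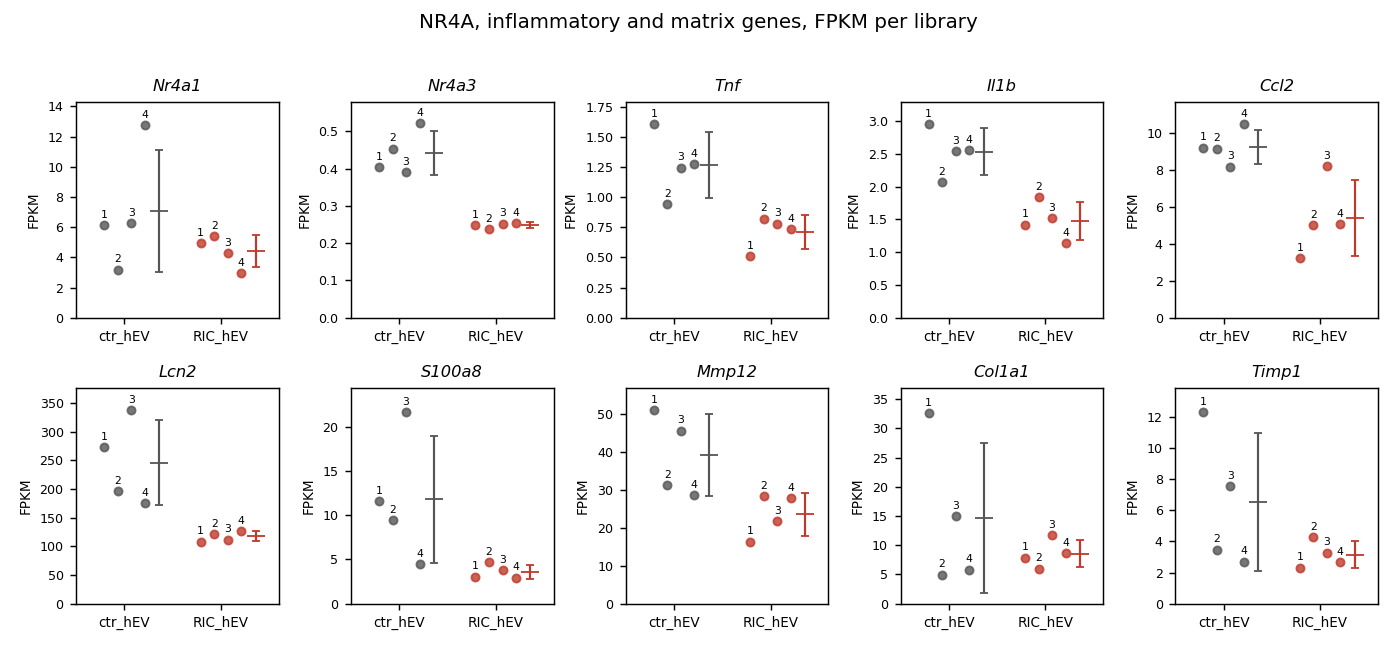
FPKM (vertical axis, from 0) of 10 genes of the NR4A family, inflammation and matrix in each library; points are libraries with replicate numbers and bars the mean ± SD of 4 libraries per group. Nr4a3, Tnf, Il1b and Lcn2 lie lower in all 4 RIC_hEV libraries than in every ctr_hEV library, whereas Col1a1 and Timp1 are highest in ctr_hEV 1 and ctr_hEV 3.

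The 12 other tested lists were not called. They were endoplasmic reticulum stress (23 of 29 lower, adjusted p = 0.0793), cholangiocyte (6 of 8 lower, 0.293), acute phase (21 of 27 lower, 0.310), bile acid (13 of 23 lower, 0.359), circadian clock (9 of 17 lower, 0.406), resident Kupffer cell (7 of 15 lower, 0.415), stellate cell (12 of 15 lower, 0.416), immediate early and NR4A (18 of 25 lower, 0.535), cell cycle (20 of 23 lower, 0.624), cholesterol synthesis (14 of 22 lower, 0.625), erythroid (5 of 7 lower, 0.881) and MHC class II (8 of 10 lower, 0.881). Most tested genes were lower as fitted (median log2 change -0.11), so such counts alone do not set a list apart. The signs of median, mean and test differed in some lists. For erythroid (median -0.56) and MHC class II genes (median -0.13) the test pointed upwards, against the mean. Kupffer cell genes had a median of 0.011 and a mean of -0.025, and clock genes a median of -0.14 and a mean of 0.0074, with an upward test for both; bile acid and cholesterol genes had a negative median and mean and an upward test relative to other genes. With 1 library left out, the cholangiocyte list was called lower without ctr_hEV 2, acute phase without ctr_hEV 1 or RIC_hEV 1, endoplasmic reticulum stress without ctr_hEV 1, ctr_hEV 2 or RIC_hEV 3, and cell cycle without ctr_hEV 4 or RIC_hEV 3; the bile acid list was called higher without ctr_hEV 2 or ctr_hEV 4. Their means relative to other genes were then -0.50 for cholangiocyte, -0.25 and -0.16 for acute phase, -0.12, -0.14 and -0.13 for endoplasmic reticulum stress, -0.20 and -0.18 for cell cycle, and 0.14 and 0.16 for bile acid. Without ctr_hEV 1 and ctr_hEV 3 together, 4 of the 12 were called: bile acid (-0.21, preset adjusted p = 0.000150), acute phase (-0.27, preset adjusted p = 1.60e-06) and endoplasmic reticulum stress lower (-0.11, preset adjusted p = 0.0111), and erythroid higher (0.23, preset adjusted p = 0.0310). Among their leading members, Ccnd1 was at 61.8 ± 14.2 FPKM in ctr_hEV and 37.2 ± 4.24 in RIC_hEV, Hmgcs1 at 11.3 ± 0.521 and 8.79 ± 0.475, Steap4 at 106 ± 24.2 and 64.3 ± 12.4, and the iron exporter Slc40a1 at 28.0 ± 2.71 and 19.95 ± 1.53. These 4, together with Stard4 and Lcn2, passed adjusted over their lists alone and not over all genes. The list for other tissues had 3 tested members, of which Krt8 passed adjusted over the list alone (313 ± 73.8 and 216 ± 12.3 FPKM).

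Genes with a miR-181 seed match were slightly lower in RIC_hEV, as were genes with shuffled sequences. Of 9857 tested genes with a searched 3' UTR, 1743 had a match; their mean log2 change lay -0.040 from that of genes without, which camera called lower with the preset correlation (exact permutation p = 0.0571 over libraries). Of 100 shuffled sequences, 28 gave a lower value and 81 were called lower. Within quintiles of 3' UTR length the difference was -0.016 and was no longer called. The 3' UTR of Nr4a3 has a match.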

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

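Libraries far from the others of their group were looked for in the named genes, list scores and 4 library measures; 16 of 290 groups of 4 had one, where chance gives about 14.5. Of the tests below, the counts of called genes and lists over 35 splits were set beforehand. The comparison of genes with shared sequence had its rule set before it was run, but after the values of Gm20716 and Gm21451 had been seen. The others were chosen after the results were seen.

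In ctr_hEV 1, Igkc was low at 11.02 FPKM (gap over range 0.871), Ndufb10 high at 62.7 (0.865) and mt-Atp6 low at 829 (0.892). In ctr_hEV 2, Fabp2 was high at 110 FPKM (0.869) and the score of the list for other tissues was high (0.872). Steap4 was high in ctr_hEV 3 at 143 FPKM (0.885). In ctr_hEV 4, Slc1a4 was low at 1.03 FPKM (0.926), and Ighv1-9 was at 0.652 with the others listed at 0 (1.0). In RIC_hEV 1, Tat was high at 1345 FPKM (0.864), the cholangiocyte score was high (0.864), the mitochondrial share was 19% against 17.9% at most in the others (0.974), and Il6 was at 0.0804 FPKM with the others listed at 0 (1.0). Usp2 (10.1 FPKM, 0.836) and the other-tissue score (0.899) stood apart in RIC_hEV 3. In RIC_hEV 4, Tgfb1 was high at 6.11 FPKM (0.872) and mt-Atp6 was at 5271 FPKM against 1077 to 1266 in the other RIC_hEV libraries (0.898). Of the 31-base stretches of mt-Atp6, 99.5% occur in another annotated gene.

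The count of 4 genes exceeded that of every other split: 1 of the 35 splits of the 8 libraries, the real one, gave 4, and the highest other gave 2. That is the smallest share that 35 splits can give. Of the 4 genes, however, 2 are Gm20716 and Gm21451, whose levels are uncertain. The 2 others only equal the highest count of another split, and the splits were not counted again without these models. The count therefore does not decide against chance division of the libraries. The 20 list calls cannot be set apart from chance in this way: 6 of the 35 splits gave as many, with 22 the highest of the others.

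Gm20716 and Gm21451 were listed at 0 in all RIC_hEV libraries. The groups did not overlap in 3.4% of 412 tested genes with at least 90% of their 31-base stretches shared. Among the 10639 others they did not overlap in 6.02% (Fisher's exact test, p = 0.0250). By the rule set before this comparison was run, this goes against estimates for shared sequence as a whole being made differently in the groups. The share also depends on the level and spread of these genes, so it cannot exclude that, and both models are among the 412. Reads shared with overlapping or near-identical genes remain a candidate explanation, since at least 98.9% of each model's 31-base stretches lie in another gene (83.0% of Gm20716 in Adnp, 84.4% of Gm21451 in Loxl2); that alone does not say why the groups differ. These partners were chosen after their values were seen. Loxl2 (4.59 ± 2.69 FPKM in ctr_hEV and 2.85 ± 0.708 in RIC_hEV) and Adnp (9.13 ± 1.505 and 7.22 ± 0.80) were not higher on average in RIC_hEV. Loxl2 was at 8.13 and 5.21 FPKM in ctr_hEV 1 and 3. In ctr_hEV 2 and 4 it was at 2.77 and 2.25, within the 1.88 to 3.53 of RIC_hEV. Dpm1, which holds 16.45% of the stretches of Gm20716, was at 2.47 ± 0.426 and 3.77 ± 0.432 (limma adjusted p = 0.332), without overlap between the groups. A difference that touches few such genes stays open. Over all genes, 4 were listed at 0 throughout one group and above 0.2 FPKM in every library of the other, against 2 at most in any other of the 35 splits. At 0 in RIC_hEV were 3 of them, both models and 4930557K07Rik (0.291 to 0.540 FPKM in ctr_hEV). The other was the immunoglobulin gene Ighv1-85, at 0 in ctr_hEV and between 0.410 and 1.11 FPKM in RIC_hEV. These genes were chosen after their values were seen. A change in transcription of these loci was not tested.

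The tested immunoglobulin genes were higher in RIC_hEV, a family picked after the results were seen and partly filtered through its RIC_hEV values. A candidate explanation is admixed lymphoid tissue, which brings T cells as well: the T and NK cell list differed by 0.014 log2 units (SE 0.16) against 0.998 (SE 0.15) for the 20 tested immunoglobulin genes. Its most abundant member, Ccl5, was at 6.53 ± 2.70 FPKM in ctr_hEV and 7.13 ± 2.09 in RIC_hEV. The T cell receptor genes Trbc1 (2.01 ± 0.849 and 1.80 ± 0.549) and Trbc2 (3.79 ± 1.48 and 3.43 ± 1.52), chosen after their values were seen, were not higher either, which goes against admixture. With 4 tested list members at low FPKM this cannot be told apart from a rise in antibody-secreting cells or in their output, which is equally untested.

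Inflammatory and matrix lists were lower in RIC_hEV. The 2 control libraries that stand apart could account for 2 of these lists: without ctr_hEV 1 and ctr_hEV 3 the score difference went from -0.32 to 0.0019 for NASH macrophage genes and from -0.28 to 0.16 for fibrosis genes. These 2 libraries hold the highest scores of both lists, so leaving them out had to raise both differences. They do not account for the whole of the chemokine difference, which went from -0.25 to -0.20 (SE 0.060). That SE rests on 2 control libraries, and the 2 left out hold the highest scores of this list too. For the neutrophil list, which went from -0.75 to -0.45 (SE 0.31), their part cannot be told apart from a difference between the groups, since the value left lies within 2 standard errors of 0. A lower share of all cells other than hepatocytes would lower endothelial genes alike; the macrophage and neutrophil lists lay -0.67 (SE 0.27) from the endothelial list, but with an exact permutation p of 0.0857 and -0.31 without the 2 libraries, so it cannot be told apart from a change in particular cells. The endothelial and Kupffer cell scores were themselves higher, by 0.14 (SE 0.083) and 0.073 (SE 0.10). The stellate cell and cholangiocyte differences were -0.087 (SE 0.097) and -0.33 (SE 0.25). Each of these lies within 2 standard errors of 0, and the Kupffer sign turned in some settings. These scores therefore do not decide whether the share of all such cells was lower. An effect of the vesicles stays open.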

How the results depend on the processing

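The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.052, 0.12, -0.0085 and -0.23, and with the replicate number as a block 3 genes and 19 lists were called, against 4 and 20. A pseudocount of 0.1, TPM scaling, no trend and a robust trend gave 4 genes, median centring and quantile normalization 6. Other settings gave 2 (no filter), 1 (mean FPKM of at least 5), 15 (array weights), 8 (without ctr_hEV 1 and 3 together, chosen after seeing the data) and 0 genes by exact permutation per gene (lowest adjusted p = 0.438, with 662 genes at the smallest possible p of 0.0286); leaving out single libraries gave 1 to 176. List calls were 13 with quantile normalization, 0 with an estimated correlation, 0 with fry and 0 in permutation tests of list scores; single libraries left out gave 16 to 23. Without ctr_hEV 1 and 3 there were 14: of the 20 lists, 8 were called in the same direction, 7 were no longer called, and 5 changed sign, of which 2 were called, fibrosis higher and xenobiotic P450 lower. The miR-181 difference was -0.048 for 8-base sites and -0.016 within length quintiles. Of 106 named genes, 89 kept their direction in every setting run, and of 20 called lists 13 did. The cause was not tested for any of these, apart from the smaller number of genes or libraries tested where a setting leaves some out. Genes below the filter were not run with quantile normalization, array weights or the block, and with 7 libraries their permutation test cannot pass.

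Signs below are log2 changes as fitted, for lists relative to other genes except with fry, where they are the plain mean. With a pseudocount of 0.1, signs turned for MHC II dendritic list (0.016). With no filter, signs turned for cholesterol synthesis list (-0.0092). With a filter of mean FPKM at least 5, signs turned for Kupffer resident list (-0.031). With median centring, signs turned for Tgfb1 (0.017), Fasn (0.0066), Ppara (0.066), Nr4a2 (0.041). With TPM scaling, signs turned for Cpt1a (-0.0059), MHC II dendritic list (0.0086). With quantile normalization, signs turned for Tgfb1 (0.0070), Fasn (0.010), Cpt1a (-0.019), Kupffer resident list (-0.0018), bile acid list (-0.010), ribosomal protein list (-0.029). With array weights, signs turned for Nkg7 (0.092), Cpt1a (-0.0023). With fry, signs turned for Kupffer resident list (-0.025), cholesterol synthesis list (-0.058), lipid droplet uptake list (-0.013), bile acid list (-0.039). Leaving out ctr_hEV 1 and 3 turned Il7r (0.079), Fabp2 (-0.031), Col1a1 (0.55), Col3a1 (0.37), Acta2 (0.058), Timp1 (0.0022), Tgfb1 (0.15), Adgre1 (0.071), Srebf1 (0.11), Fgf21 (0.13), Il6 (-0.017). It also turned the lists fibrosis ECM (0.16), stellate cell markers (0.051), NASH macrophage (0.0019), Kupffer resident (-0.013), MHC II dendritic (0.079), cholangiocyte (0.093), erythroid (0.23), interferon response (-0.049), cholesterol synthesis (-0.019), bile acid (-0.21), xenobiotic P450 (-0.28), cell cycle (0.017), circadian clock (-0.0032), pericentral (-0.14). With single libraries left out, these changed sign within the range given: Col1a1 (-0.72 to 0.11), Tgfb1 (-0.21 to 0.029), MHC II dendritic list (-0.045 to 0.040), bile acid list (-0.055 to 0.16), cell cycle list (-0.20 to 0.0067), Il6 (-0.022 to 0.021), Cpt1a (-0.016 to 0.13), Nr4a2 (-0.18 to 0.016), Scd1 (-0.0062 to 0.23).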

Other observations

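All tests in this part except the miR-181 comparison, and all genes named outside the rule, were chosen after the data were seen.

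Immunoglobulin genes were also examined as a family. All 20 tested immunoglobulin genes were higher in RIC_hEV, 7 without overlap between groups (chance gives 2.86%, and 5.87% of all tested genes showed it) and 15 at an unadjusted limma p under 0.05. Their summed FPKM was 39.42 ± 10.53 in ctr_hEV and 108 ± 13.4 in RIC_hEV (SD, n = 4 per group). Their mean log2 difference relative to all genes was 0.998, and 0.87 without ctr_hEV 1 and ctr_hEV 3. The family was picked because some of its members led the ranking, so these values describe it and test nothing. The filter on the mean of all 8 libraries also admits low members through their RIC_hEV values, such as Ighv1-9 (0.163 and 2.10 FPKM). The 20 of 20 higher is therefore partly set by the filter. By isotype, which was not tested as a difference, mean FPKM in ctr_hEV and RIC_hEV was 3.73 and 18.0 for Ighg2c, 2.35 and 4.31 for Igha, 2.22 and 2.96 for Ighm, and 0.762 and 0.265 for Ighg1, which lay below the filter. The B cell receptor gene Cd79a stayed low, at 0.318 ± 0.0968 and 0.319 ± 0.121 FPKM (exact permutation p = 1.0). Other genes that plasma cells express did not all go the same way. Mzb1 was at 0.246 ± 0.195 and 0.519 ± 0.180 FPKM (exact permutation p = 0.114) and Derl3 at 0.208 ± 0.0563 and 0.305 ± 0.155 (exact permutation p = 0.286). Sdc1 was at 62.2 ± 15.2 and 58.5 ± 2.67, and Xbp1 at 20.44 ± 2.41 and 15.7 ± 0.660, lower in every RIC_hEV library than in any of ctr_hEV. Both lay far above Jchain (1.31 and 3.03 FPKM), and Xbp1 is also in the endoplasmic reticulum stress list. In whole liver these 2 genes need not reflect plasma cells.

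Several transcripts marked the 2 control libraries that stand apart. H19, an imprinted fetal RNA, was at 20.8 and 23.1 FPKM in ctr_hEV 1 and 3, at 5.02 and 1.29 in ctr_hEV 2 and 4, and between 0.388 and 0.990 in RIC_hEV. Epcam was at 9.10 and 4.96 FPKM in ctr_hEV 1 and 3 and between 0.89 and 1.2 in the 6 other libraries. The urinary protein gene Mup3 was at 20.6 and 28.5 FPKM in those libraries, at 132 and 143 in ctr_hEV 2 and 4, and between 154 and 183 in RIC_hEV. The libraries were not regrouped on these values.

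Genes with long 3' UTRs lay lower in RIC_hEV on average than genes with short ones, but not by a difference that passed. The mean log2 change went from -0.065 in the shortest quintile of 3' UTR length (median 215 bases) to -0.15 in the longest (median 3489). The difference of the longest and shortest quintile between groups was -0.084 (exact permutation p = 0.114).

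Delivery of miR-181 by the vesicles was considered as a hypothesis. It predicts genes with a seed match below nearly all shuffled sequences; 72 of 100 shuffled sequences gave a value at or above theirs and 28 a lower one, short of the 95 set before the data were examined, so these data do not bear it out. Matched genes have longer 3' UTRs (median 2289 against 902 bases).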
